A study of Danio rerio with 4 samples.

How the data were processed

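Genomic DNA from hearts dissected from wild-type zebrafish (Danio rerio) embryos at 48 hours post fertilisation was profiled for 5-hydroxymethylcytosine (5hmC), the base made when TET enzymes oxidise 5-methylcytosine. Per the labels' protocols, 5hmC in sheared DNA was tagged with an azide-bearing glucose by beta-glucosyltransferase, biotin was attached by click chemistry, and the tagged fragments were captured on streptavidin beads and amplified with 12 PCR cycles. Input libraries were made from DNA that was not captured. The series held 4 samples, 2 captures and 2 inputs, each numbered 1 and 2 in the titles. Peak lists of the 2 captures were used. Values from the input libraries were not analysed here.

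Reads were adapter trimmed and aligned with BWA, per the labels' protocols, and the submitters' processing notes name BWA and the danRer7 genome build. Peak names in the deposited files carry the name of the peak caller MACS. Its version, its settings and whether the input served as control are not given in the sources used here. Each capture had its own list. The deposited files hold, for each peak, a start and end in base pairs and a score made by the authors' peak caller. The lowest deposited score was 50.0 in both lists, and neither a header nor a label states the scale of the score. Its range is like that of a log-transformed p-value, so a score ratio may not be a ratio of 5hmC. The score served to rank and filter peaks. Medians, ratios and a log10 correlation of scores are also given, and they describe the scale as deposited. Values of the same rank in the 2 lists were not assumed to stand for the same amount of 5hmC. The read depth behind a peak is unknown from the files, while the labels' protocols state about 30M reads per library as the sequencing depth. No count model and no test between conditions was possible, since the series has 1 condition and the files hold no read counts.

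Peaks were compared with interval functions written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. A peak was called shared if it overlapped a peak of the other list by at least 1 bp. The share was set against 1000 random placements, in which the second list was shifted circularly along each chromosome by a random distance, so that widths and spacing were kept. A second set of 1000 placements moved it by 20 to 100 kb only, which keeps regional density, and was added after the data had been examined. A Jaccard index gave the shared bases over the bases in either list. Wilson intervals at 95% accompany shares of peaks; they treat peaks as independent and cover counting error only. Consensus regions were made by merging overlapping peaks of both lists and keeping the regions to which both contributed. Scores were compared over pairs in which each peak overlapped no other peak. Correlations across peaks or windows carry no p-value, because peaks and windows are not independent replicates. Densities used windows of 1 Mb, counted by the midpoint of each region, and chromosome spans that end at the last peak end of either list; the 25 spans add up to 1356.8 Mb. Coordinates are given counted from 1 on danRer7.

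Rules for the regions and windows named were fixed before the data were examined: the 10 consensus regions with the highest mean score rank over both lists, the 10 widest, and the 5 windows of 1 Mb with the most and the 5 with the fewest consensus regions. The design also held comparisons by gene feature, around transcription start sites, by gene list and by base composition. A genome and annotation of the danRer7 build were not used here, and coordinates were not converted between builds, so those comparisons were not made and no peak is assigned to a gene. Alternatives covered the score threshold, the overlap that counts as shared, merging of peaks within 500 bp, lists of equal length, the window size, covered bases in place of peak number, and each list alone. The overlap functions were tested on simulated data. Lists of 22596 peaks made to share 19.99%, 50.0% and 80.01% of their peaks gave those shares exactly. For a simulated second list placed uniformly at random along each chromosome, independent of replicate 1, 26.16% of the peaks overlapped. The mean of 100 shifts was 26.03%. That list had no regional clustering, so this does not test circular shifts of lists that cluster in the same regions.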

Results

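The series profiled 5hmC in the embryonic zebrafish heart in 2 capture libraries from wild-type embryos at 48 hours post fertilisation. Each biological group was a pool of 40 or more hearts, per the labels, and the labels do not say whether the 2 pools came from separate clutches. Spread between the lists may therefore be technical. There was 1 condition, so the comparisons were of the 2 captures with each other and of regions of the genome within them. Read totals per library were not in the files, and depth behind single peaks is unknown.

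Peaks of the 5hmC captures were numerous and covered a similar percentage of the chromosome spans in both lists. Replicate 1 had 145501 peaks that covered 197.3 Mb, or 14.5% of the chromosome spans. Replicate 2 had 145893 peaks that covered 211.4 Mb, or 15.6%. Peaks lay on all 25 chromosomes, and no peaks overlapped within a list. The median distance between neighbouring peaks was 3114 bp in replicate 1 and 3047 bp in replicate 2. The median peak width was 1169 bp (quartiles 896 and 1610 bp) in replicate 1 and 1235 bp (quartiles 942 and 1717 bp) in replicate 2. Scores had a median of 103.7 in replicate 1 and 108.3 in replicate 2, and wider peaks tended to score higher (Spearman's rho across peaks 0.46 and 0.47).

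The first comparison asked how far the 2 captures marked the same regions. Most peaks were found in both. In replicate 1, 114966 peaks (79.0%, Wilson interval 78.8 to 79.2%) overlapped a peak of replicate 2. In replicate 2, 112951 peaks (77.4%, Wilson interval 77.2 to 77.6%) overlapped a peak of replicate 1. Under 1000 circular shifts the same shares averaged 27.9% and 27.6%, and none exceeded 29.2% and 28.8%. Shifts of 20 to 100 kb, which keep regional density, gave 37.3% and 36.7% on average and at most 38.4% and 37.7%. The lists had 153.0 Mb in common out of 255.7 Mb in either, a Jaccard index of 0.598 against a mean of 0.0825 under circular shifts and 0.125 under shifts of 20 to 100 kb. Merging overlapping peaks gave 110315 consensus regions, which covered 186.8 Mb (13.8% of the spans) with a median width of 1436 bp.

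Sharing rose with score along the whole range of both lists. In the lowest score decile, 49.0% of replicate 1 peaks and 45.1% of replicate 2 peaks were shared. In the fifth score decile the shares were 78.8% and 76.7%, and in the highest 99.8% and 99.9%. The 30535 unshared peaks of replicate 1 had a median score of 67.7 against 122.4 for shared peaks, and a median width of 955 bp against 1241 bp. The 32942 unshared peaks of replicate 2 had a median score of 69.3 against 130.2, and a median width of 1010 bp against 1318 bp. Across 104435 pairs of peaks that overlapped only each other, Spearman's rho of the scores was 0.65 (0.62 to 0.69 within chromosomes) and Pearson's r of the log10 scores was 0.72. Spearman's rho of their widths was 0.82. The quartiles of the replicate 2 score over the replicate 1 score were 0.771 and 1.42, so a score difference of that size at 1 region lay within the spread between the captures.

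**Figure D1:**
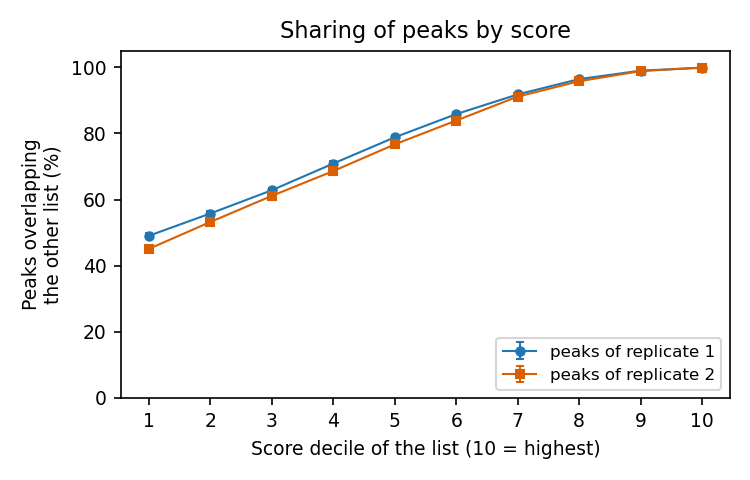
Percent of peaks that overlap the other list by at least 1 bp (y axis) in each score decile of a list (x axis, 10 is the highest), for replicate 1 (circles) and replicate 2 (squares); bars are 95% Wilson intervals. The share rises from 49.0% and 45.1% in the lowest decile to 99.8% and 99.9% in the highest.

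The regions strongest in both captures together were picked by their mean score rank over the lists, so that high ranks in both follow from the choice. Chromosome 22 held 4 of the 10 consensus regions with the highest mean score rank and chromosome 13 held 2. First by mean rank was chromosome 22, 38793824 to 38804162, with a score of 2360 in replicate 1 and 2639 in replicate 2. It was followed by chromosome 21, 28191715 to 28199186, which scored 3100 and 2402. A score of exactly 3100 was held by 1 peak of replicate 1 and 2 of replicate 2, so it may be a value assigned by the caller rather than a measured one. On chromosome 22, the regions at 11262427 to 11277055 and 11291534 to 11301723 scored 2184 and 2194 in replicate 1, and 3100 and 2409 in replicate 2. The region at 33030902 to 33038739 of the same chromosome scored 2075 and 2419. On chromosome 13, neighbouring regions at 5182289 to 5216796 and 5218761 to 5230344 reached 2136 and 2222 in replicate 1, and 2843 and 2634 in replicate 2. Single peaks in both lists made up the regions on chromosome 9 (8489212 to 8494979), chromosome 6 (11742233 to 11748398) and chromosome 10 (28881628 to 28886203), whose scores lay between 2091 and 3166. A region could rank high in 1 list alone: chromosome 4, 7317344 to 7334376, held the peak ranked 5 in replicate 1 (score 2510), while its replicate 2 peak scored 97.9, below the median of that list.

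**Figure D2:**
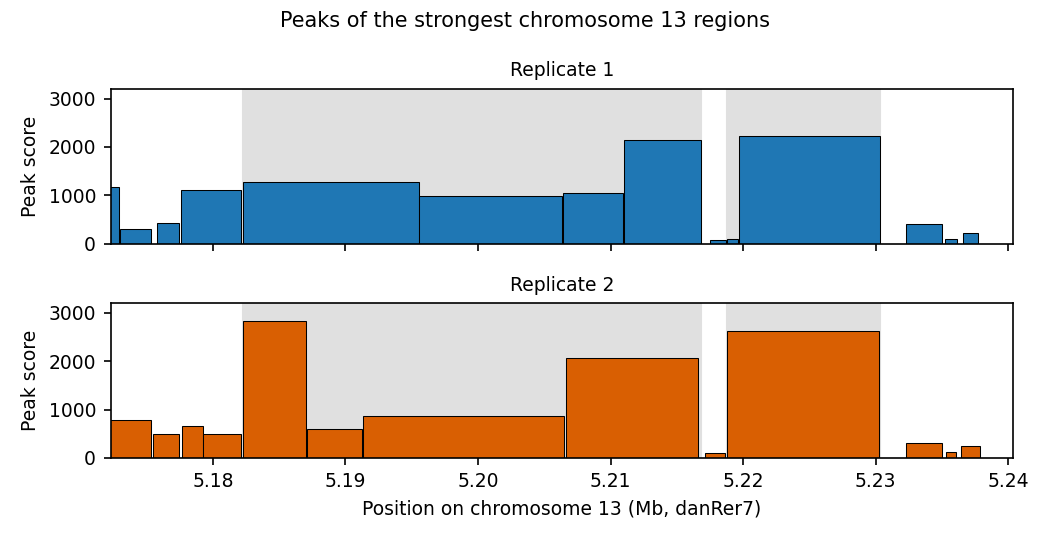
Peaks on chromosome 13 around the regions 5182289 to 5216796 and 5218761 to 5230344 (shaded) in replicate 1 (top) and replicate 2 (bottom); the x axis is the danRer7 position in Mb, each box spans a peak and its height is the peak score. The first region is divided into 4 peaks in each list, at different positions, while its outer limits nearly coincide.

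Wide regions were rare. Of the consensus regions, 1368 were wider than 5 kb and 73 wider than 10 kb. The widest was the chromosome 13 region at 5182289 to 5216796 (34508 bp), made of 4 peaks in each list, and it was the only one of the 10 widest that was also among the 10 strongest. Chromosome 8 followed with 55684980 to 55704749 (19770 bp, scores 733 and 716), then chromosome 14 with 7097280 to 7115606 (18327 bp, scores 688 and 1156). Chromosome 4 held the next, at 7662114 to 7680324 (18211 bp, scores 985 and 1367) and at 7317344 to 7334376 (17033 bp). The latter was divided into 4 peaks in replicate 1 and was 1 peak in replicate 2. The remaining 5 lay on chromosomes 3 (54177790 to 54194491), 7 (70503601 to 70519737), 20 (8142290 to 8157653), 22 (11331278 to 11346291) and 25 (35677536 to 35692466), and were 14931 to 16702 bp wide.

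The last comparison concerned the distribution of 5hmC regions over the genome. Chromosome 23 was the densest, with 99.8 consensus regions per Mb (127.4 peaks per Mb in replicate 1 and 128.6 in replicate 2). Chromosome 4 was the sparsest, with 55.9 consensus regions per Mb (72.7 and 73.8 peaks per Mb). The ratio between them was 1.78. Chromosomes 18, 13 and 11 came next to chromosome 23 with 95.5, 94.7 and 94.1 consensus regions per Mb, and chromosomes 1 and 2 next to chromosome 4 with 66.7 and 70.9. The 2 captures differed little in these densities compared with the differences between chromosomes. Over 1344 windows of 1 Mb, Spearman's rho of the peak numbers of the 2 lists was 0.98.

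**Figure D3:**
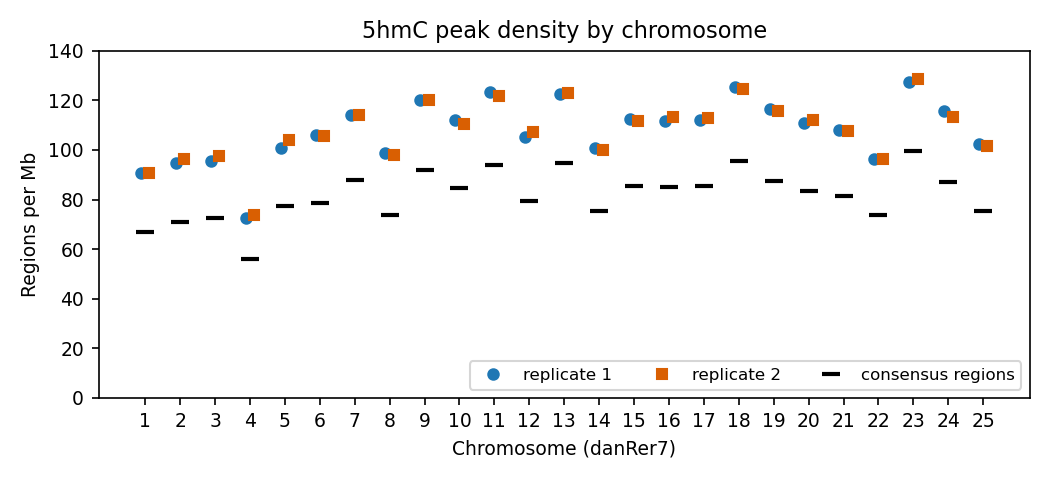
Number of 5hmC peaks per Mb of chromosome span (y axis) on each of the 25 chromosomes (x axis) in replicate 1 (circles) and replicate 2 (squares), with consensus regions as bars. Chromosome 4 is lowest in both lists (72.7 and 73.8 peaks per Mb) and chromosome 23 highest (127.4 and 128.6).

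The median window held 78 consensus regions (quartiles 52 and 108). The densest window was chromosome 11, 22 to 23 Mb, with 249 consensus regions that covered 46.3% of it. Chromosome 24 had 248 between 1 and 2 Mb and 243 between 4 and 5 Mb, which covered 44.5% and 44.4%. Chromosome 23 had 245 between 23 and 24 Mb, covering 50.6%, and chromosome 13 had 217 between 34 and 35 Mb, covering 36.7%. The 5 emptiest windows were all on chromosome 4, starting at 30, 32, 42, 43 and 49 Mb, and had 2 consensus regions each; 3 to 6 peaks of replicate 1 and 7 to 12 of replicate 2 fell in them.

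These windows belonged to a long stretch of chromosome 4 with few 5hmC regions, from about 28 Mb to the last peak at 62094438. The stretch was not uniform: its 34 windows held a median of 5 consensus regions and a maximum of 29, with the densest near its far end. Values for the stretch pool all of these windows. Over the genome, 68 windows had under 20 consensus regions, of which 32 were in the stretch and the rest elsewhere. The long arm of zebrafish chromosome 4 is known as a repeat-rich, heterochromatic arm. The boundary at 28 Mb was chosen after the values had been seen. Replicate 1 had 345 peaks there (10.1 per Mb against 109.7 elsewhere) and replicate 2 had 423 (12.4 per Mb against 110.0 elsewhere), which are densities 10.8 and 8.86 times lower. Consensus regions were 13.1 times less dense (6.34 against 83.2 per Mb), and 24.998 times less dense when only peaks above the median score of each list were used. The sparsest stretch of 34 windows on any other chromosome had 79.1 peaks per Mb in replicate 1 and 80.2 in replicate 2. Peaks that were called in the stretch had a median score of 78.6 in replicate 1 and 78.0 in replicate 2, against 103.9 and 108.4 elsewhere. Of these peaks, 63.5% (Wilson interval 58.3 to 68.4%) and 51.5% (46.8 to 56.3%) were shared, against 79.1% and 77.5% elsewhere. Shifts of 20 to 100 kb gave 6.46% and 5.17% in the stretch and 37.4% and 36.8% elsewhere, so chance overlap differed between them. The first 28 Mb of chromosome 4 averaged 148.9 and 148.6 peaks per Mb, near the densest stretch of that length on any other chromosome (148.4 and 150.8). In the last windows before 28 Mb both lists were already below these averages.

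**Figure D4:**
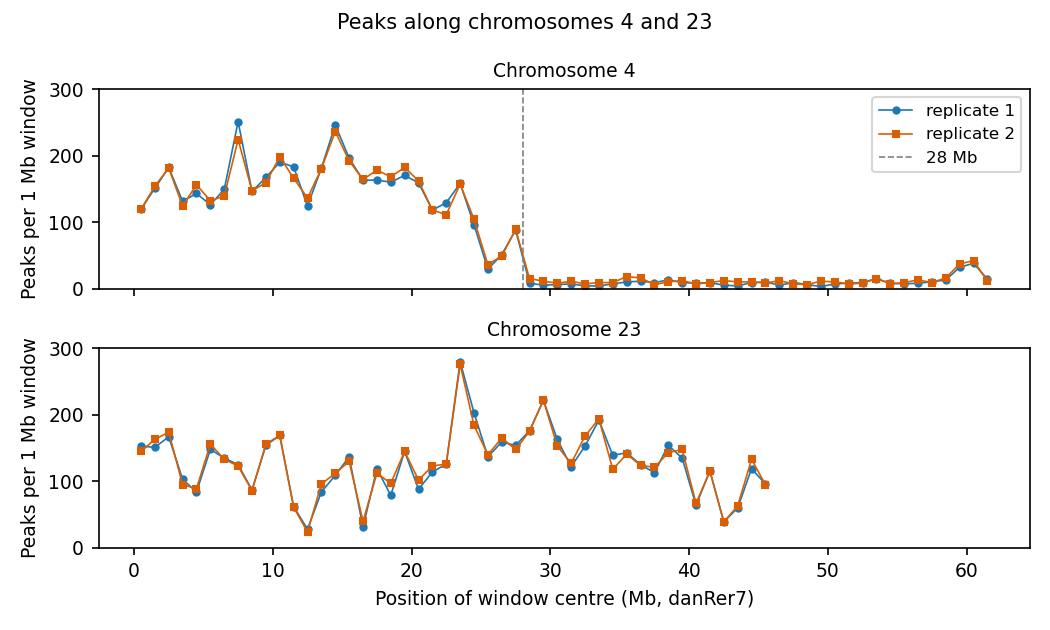
Peaks per 1 Mb window (y axis) along chromosome 4 (top) and chromosome 23 (bottom) by position of the window centre in Mb (x axis), for replicate 1 (circles) and replicate 2 (squares). On chromosome 4 the lists average 148.9 and 148.6 peaks per Mb before 28 Mb (dashed line) and 10.1 and 12.4 after it. Both lists are already below the first averages in the last windows before the line, so the fall is not a single step.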

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

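The alternatives for the chromosome 4 stretch, and leaving out chromosome 4 or that stretch, were chosen after the data had been examined. Of 47 alternative values, 27 stayed near the reported value and 20 moved. None reversed a called direction, but peak numbers, covered lengths and shared percentages have no direction that could reverse. Near means within 1.5 times for peak numbers and covered lengths, and within 1 SD between the lists or between chromosomes for other values, so small shifts of ratios count as moved. Merging peaks within 500 bp left 129187 and 128531 peaks. Keeping only peaks above each list's median score left 72748 and 72946 peaks over 117.1 and 126.3 Mb. It gave shared percentages of 74.4 and 73.2, since partners below the median were also removed. It lowered rho of the scores to 0.60 and raised the chromosome density ratio to 1.83 and the ratio for the chromosome 4 stretch to 24.998. With only the top 10% of each list, 65.8% and 64.9% were shared, since a partner then had to be in the top 10% too. Requiring an overlap of 50% of both peaks gave 72.7% and 72.5%, and a score ratio of shared to unshared peaks of 1.74 and 1.79 in place of 1.81 and 1.88. Covered bases in place of peak number gave a chromosome density ratio of 1.88. With each list alone that ratio was 1.74 to 1.75 and the ratio for the chromosome 4 stretch 8.86 to 10.8, both below the consensus values; chromosome 23 was the densest and chromosome 4 the sparsest in each. The assembled-chromosome setting changed nothing, because no peak lay on another sequence, so its values are among the 27 by construction. No paired analysis was possible because the input samples, which carry the same replicate numbers, had no values analysed here. The files give no read depth, so a region without a peak is not shown to lack 5hmC: 51.0% and 54.9% of peaks in the lowest score decile had no partner in the other list.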

Other observations

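The chains of regions, the chromosome ends and the tests on the chromosome 4 stretch and on joined peaks were chosen after the data had been seen. Consensus regions gathered into long chains. When regions no more than 5 kb apart were linked, 671 chains exceeded 50 kb. In 100 draws that placed each region at random within its own 1 Mb window, which keeps regional density, 69 to 114 chains exceeded 50 kb (mean 88.7). Placement along whole chromosomes gave a mean of 2.24, but it ignores the differences in regional density. The longest ran from 9341595 to 9606384 on chromosome 12 (264.8 kb), with 68 regions covering 67.0% of it. The next were on chromosome 4 (7573937 to 7826403, 71 regions, 65.8% covered), chromosome 18 (30206927 to 30411926, 62 regions), chromosome 1 (40727948 to 40930199, 54 regions) and chromosome 25 (619548 to 821365, 57 regions). The length of the longest chain lay within the range of the draws within windows, whose longest had a median of 166.9 kb and reached 292.6 kb. The longest of a draw could lie in any window, so this does not test a chain against the density of its own window. At the other extreme, the 5 longest stretches without a peak in either list were all on chromosome 4 beyond 28 Mb; the longest, 55269682 to 55871474, was 601.8 kb.

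Neighbouring consensus regions had weakly similar score ranks (Spearman's rho across regions 0.17). The value was 0.077 for neighbours more than 5 kb apart, where 1000 shuffles within chromosomes gave at most 0.016, and 0.016 for those more than 20 kb apart. The first Mb of a chromosome had more peaks per Mb than its inner part on 19 of 25 chromosomes in replicate 1 (median ratio 1.27, exact two-sided sign test p = 0.015) and 18 of 25 in replicate 2 (median ratio 1.18, exact p = 0.043). With Benjamini-Hochberg adjustment over the 4 exact tests of both ends and both lists, neither passed (adjusted p = 0.058 for both), and the last Mb was higher on 18 and 17 of 25 chromosomes (adjusted p = 0.058 and 0.11).

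Peaks called in one capture alone may include regions near the score threshold that crossed it in one list. The prediction, fixed before the values were seen, was that under 5% of the top score decile would be unshared, and the higher of the 2 lists had 0.151%. Weak spurious calls in 1 list would also meet that prediction, so it does not tell them from regions near the threshold. Small displacements of edges do not account for most unshared peaks. At most 7.10% of them lay within 250 bp of a peak of the other list, against about 5.4% for shifted peaks that missed it. Losses on particular chromosomes do not either, since the shared percentage varied by at most 5.49 points over the 24 chromosomes other than 4. A few strong peaks remain: 22 of replicate 1 and 10 of replicate 2 in the top decile. On chromosome 19, 4 adjacent replicate 1 peaks with scores of 70.7 to 698.1 filled 46987135 to 47004032, while replicate 2 had no peak between 46986684 and 47005085 but had peaks on both sides. In the other direction, 9 adjacent replicate 2 peaks with lower scores (60.7 to 136.4) lay at 12830768 to 12883468 on chromosome 24 (52.7 kb), where replicate 1 had no peak. The strongest unshared peak was on chromosome 25 (28547706 to 28554724), with a score of 770.4 in replicate 1. Whether the animals, the library or the caller made these gaps was not tested.

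The scarcity of peaks on chromosome 4 beyond 28 Mb was present in both lists, with a density at most 0.113 times that elsewhere in either. It was therefore not confined to 1 library. The stretch was chosen after these values had been seen, so they are no test of a low yield. Long blocks in which no reads can be placed would leave peaks in islands, with a low ratio of median to mean gap. That ratio was 0.459 in the stretch, above the 0.290 to 0.394 of the other chromosomes, so its consensus regions were spaced more evenly than theirs. Such blocks are not excluded by this, because the ratio also depends on how closely regions cluster, and regions elsewhere were far denser. Repeats scattered through the stretch, where uniquely placed reads could be few, also stay open, because neither the sequence nor the reads were analysed here. Whether many of the remaining calls are spurious cannot be told from these lists. Their shared percentage was as low as 0.665 times that elsewhere, and part of this goes with the lower chance overlap there. Peaks of like scores elsewhere would give 69.9% and 67.4% in place of the observed 63.5% and 51.5%. As a share of the excess over chance that was possible, sharing reached 61.0% and 48.9% in the stretch against 66.6% and 64.4% elsewhere, so it was lower in both lists, and more so in replicate 2. A truly low 5hmC level there is a further possibility that was not tested, since neither the reads nor the input libraries were analysed here.

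The chromosome 4 region at 7317344 to 7334376 scored 2510 where replicate 1 divided it and 97.9 where replicate 2 joined it. A candidate explanation was that joining peaks lowers the score. Of 4383 replicate 2 peaks that overlapped 2 or more of replicate 1, 3346 were compared. Their joined score was a median of 1.402 times the highest divided score and was lower in 24.96% of them. Of 2573 replicate 1 peaks that overlapped 2 or more of replicate 2, 1571 were compared. Their joined score was 1.18 times the highest divided score, and lower in 34.7%. Relative to neighbouring one-to-one pairs, the 2 ratios were 1.302 (bootstrap interval 1.27 to 1.33) and 1.29 (1.25 to 1.33). The intervals come from 1000 resamples within these lists and do not cover the spread between captures. However, peaks may be joined more readily where a list has more signal, so the choice of joined peaks could raise these ratios by itself. That possibility was not tested. The explanation stays open, and so does the discordance of this region.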
